A study of Mus musculus with 12 samples.

How the data were processed

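RNA of CMT-93 cells was sequenced in 12 libraries, 3 in each of 4 groups given by the treatment label: control, PTSO, T. muris antigens, and PTSO followed by T. muris antigens. PTSO at 20 µM, or its vehicle, went on 30 minutes ahead of the antigens at 100 µg/mL, and cells were collected 6 hours later. The labels name total RNA and a Qiagen column kit, and do not say whether the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples. The series title names LPS, while the sample labels and the design text name T. muris antigens, and the groups follow the sample labels.

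The authors deposited one table of raw read counts, with one column per library and one Ensembl gene identifier per line. The values were whole numbers with totals that differed between libraries, and they were used as counts without further change. The submitters' processing notes name HISAT, DESeq2 and the mm39 build, with no versions and no roles. The program that counted the reads, the annotation release and the strand setting are not given in the sources used here.

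The table held 55137 gene identifiers, of which 1336 were unannotated loci with 0.351% of the counts and 25928 had no count in any library. Gene symbols were taken by identifier from a reference annotation in which 53620 of the identifiers were found. The symbol in the table differed from it for 1605 identifiers, 14 of them symbols that a spreadsheet had turned into dates. That annotation belongs to an earlier genome build than the one the submitters name, so no coordinates are given, and it served for symbols, transcript length and GC content alone. Unannotated loci stayed in the tests and are not named.

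Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 15267 genes with 99.93% of the counts, 413 of them unannotated loci. Libraries were scaled by TMM. One negative binomial model with one coefficient per group was fitted to all 12 libraries, which leaves 8 residual degrees of freedom, and each comparison was tested with edgeR's quasi-likelihood F-test with robust dispersion. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The common dispersion was 0.00764, a biological coefficient of variation of 8.74%. The SE given with a log2 fold change is its size divided by the square root of F, an approximation. CPM values are scaled by TMM and given as mean ± SD of 3 libraries. The work ran in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

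The comparisons were PTSO against control, T. muris against control, PTSO + T. muris against T. muris, PTSO + T. muris against PTSO, PTSO + T. muris against control, and the interaction, which is the PTSO effect with antigens minus the PTSO effect without them. The PTSO effect was also correlated across genes between backgrounds, as was the T. muris effect. The comparisons in each correlation share no library, and genes are not independent replicates.

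There were 27 gene lists with 511 entries: NRF2 targets and antioxidant defence, heat shock response, endoplasmic reticulum unfolded protein response, ATF4 integrated stress response, metal response, NF-kB targets and inflammatory cytokines, interferon-stimulated genes, antigen presentation, type 2 epithelial response, immediate early and MAPK feedback genes, epidermal growth factor ligands and wound repair, mucus and goblet cell genes, tight junction and adhesion, antimicrobial defence, cholesterol synthesis, glycolysis and hypoxia, mitosis, DNA replication, p53 targets, aryl hydrocarbon receptor targets, Wnt targets and intestinal stem cell genes, proteasome subunits, enterocyte genes, ribosomal proteins, mitochondrially encoded transcripts, leukocyte markers, and fibroblast and endothelial markers. The 25 lists with at least 3 tested genes were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes tested. It was repeated with a correlation estimated for each list, and fry was run as a test of a list's genes alone. The counts "adjusted over the list alone" come from the same gene p-values, adjusted within the list.

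The design, the lists, the tests and the rule for naming genes were set before the data were examined. In PTSO against control, T. muris against control and PTSO + T. muris against T. muris, the rule names the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 in which no library of one group overlaps the other, an arrangement that chance gives in 10% of 3 against 3 splits. It also names up to 4 members by smallest p of each list that passed its test or held a called gene. The other comparisons name 4 rises and 4 falls, or the 4 smallest p-values when fewer than 4 genes were called. Symbols that are only identifiers or clone names were passed over, and some genes that the rule picks are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

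The fit was checked on simulated counts with this depth and dispersion. Between 49% and 68% of 1.5-fold changes and between 63% and 81% of 2-fold changes were called, depending on the comparison. False calls were 1 to 15 among 113 to 153. In each comparison of 2 groups false calls were a larger share than the threshold for a call aims at. They were 8 among 131 for PTSO against control and 10 among 146 for T. muris against control. For PTSO + T. muris they were 15 among 153 against T. muris, 8 among 152 against PTSO and 11 among 153 against control. The 1 among 113, in the interaction, is a smaller share. The check covers depth and dispersion, not a gap among the control libraries. Its rates therefore cannot vouch for the comparisons that use those libraries. Depth per library ranged from 16.7 to 34.5 M counts. Intervals at 95% for summed counts of genes with few reads are exact Poisson intervals and cover counting error only.

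The alternatives set beforehand were DESeq2 1.42.0, limma voom, DESeq2 size factors in the edgeR fit, no filter on low counts, a filter at a CPM of at least 1 in at least 3 libraries, a fit with only the groups compared, the replicate number as a block, each library left out in turn, and a minimum absolute log2 fold change of 1. Chosen after seeing the data were a fit without control libraries 2 and 3 together, in which the lone control is assumed to vary like the other groups, and offsets for trends of each library with GC content and transcript length, which were known for 97.2% of the genes tested.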

Results

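Gene-level read counts were obtained for 12 libraries of CMT-93, an epithelial cell line from the mouse rectum. The 4 groups of 3 libraries crossed PTSO, an organosulfur compound of garlic, with antigens of Trichuris muris, the mouse whipworm. The series title names LPS instead of these antigens, and the groups follow the sample labels. Total counts were 24.6 to 25.9 M in the control libraries, 23 to 30.3 M with PTSO, 16.7 to 34.5 M with T. muris antigens and 19.6 to 26.1 M with both. Each library had counts in 19254 to 20892 genes. The mitochondrial share of counts was 0.897% to 1.57%, and the 10 most abundant genes took 3.74% to 3.99% of the counts in each library.

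Control libraries 2 and 3 stood apart from the other 10 libraries. The principal component that held 26.3% of the variance placed them at -26.7 and -33.1, control library 1 at -1.76, and the treated libraries between 0.129 and 17.4. The component with 10.8% of the variance placed the T. muris libraries at 9.52 to 15.2 and control library 1 at 6.38, with all 6 PTSO-treated libraries (-17 to -1.51) and control libraries 2 and 3 (-3.92 and -2.04) below 0. Across genes, control library 1 correlated with the treated libraries at 0.9929 to 0.9945 and with the other control libraries at 0.9909 to 0.9924. Each comparison against control therefore has its counts and list results without these libraries beside it.

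**Figure D1:**
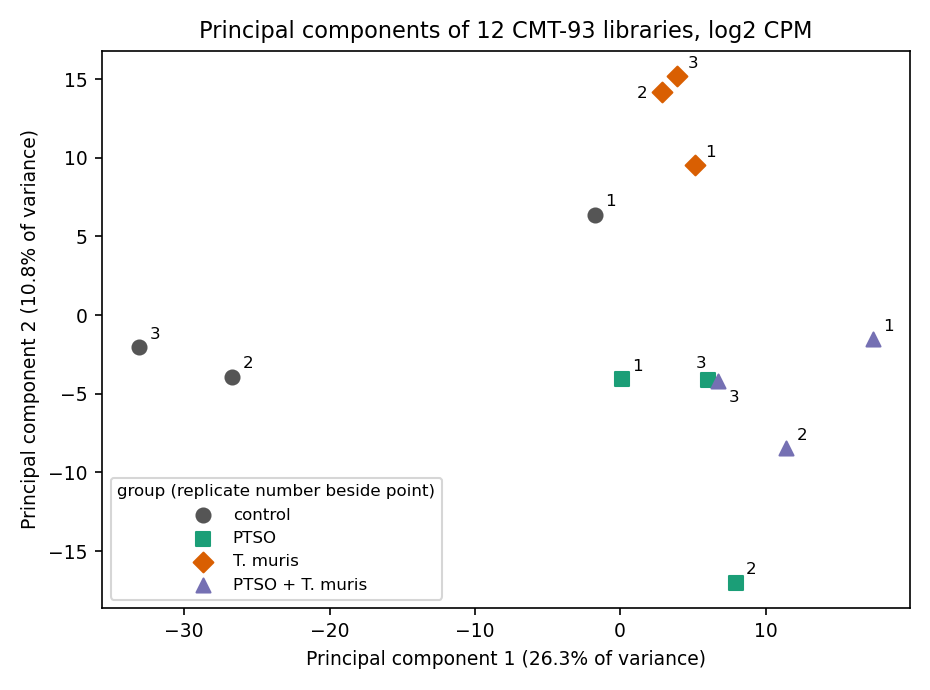
Principal components of log2 CPM for the 12 libraries, with component 1 (26.3% of variance) on the horizontal axis and component 2 (10.8%) on the vertical axis; symbols give the group and numbers the replicate. Control libraries 2 and 3 lie at -26.7 and -33.1 on component 1, and the other 10 libraries between -1.76 and 17.4.

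PTSO against control asks what the compound alone changed. Selenow (ENSMUSG00000041571), which encodes a small selenoprotein, rose from 38.8 ± 5.37 to 92.9 ± 3.88 CPM (SD, n = 3 per group), a log2 fold change of 1.26 ± 0.0826 (SE) with adjusted p = 2.84e-08. Selenoh (ENSMUSG00000076437), a nuclear selenoprotein, rose from 25.9 ± 3.04 to 62.2 ± 3.79 CPM, and Gpx1 (ENSMUSG00000063856), the cytosolic glutathione peroxidase, from 187 ± 7.56 to 316 ± 15.4 CPM. Gpx1 was singled out in this comparison after its values were seen. P2rx7 (ENSMUSG00000029468), an ATP-gated cation channel, rose 5.36-fold from 0.803 ± 0.387 to 4.31 ± 1.41 CPM with adjusted p = 0.00142. Hspa1a (ENSMUSG00000091971), an inducible heat shock protein of 70 kDa class, had 7 counts in the control libraries together, 6 of them in control library 3. This is 0.0922 CPM with an interval of 0.0371 to 0.19. With PTSO it had 479 counts, 5.84 CPM with an interval of 5.33 to 6.39. Hspa1a and its near-identical paralog Hspa1b share reads, and their summed level was 35.9 ± 6.42 CPM in control and 70.9 ± 23.9 CPM with PTSO. Hspa1b alone had adjusted p = 0.0634.

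Other large rises in PTSO against control were Fosb, a subunit of the AP-1 transcription factor (log2 fold change 1.44 ± 0.334), Dynap (1.19 ± 0.246) and the TNF receptor adaptor Traf1 (1.05 ± 0.272). The largest falls were Tmem150a (-4.24 ± 0.716), Depp1 (-1.73 ± 0.321), the potassium channel gene Kcnj2 (-1.65 ± 0.376), Ccdc33 (-1.61 ± 0.281), Hacd4 (-1.41 ± 0.318), Krtap1-5 (-1.29 ± 0.281), Prss35 (-1.28 ± 0.305) and Cib3 (-1.2 ± 0.247). Tmem150a did not fall with PTSO where antigens were given, with 71, 8 and 7 counts under antigens alone and 73, 56 and 123 under both treatments. Of the genes tested, 802 were called, 360 higher and 442 lower, and 37 of them changed by at least 1 on the log2 scale. The median size of a called change was 0.34 on that scale.

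Of the 25 lists tested in PTSO against control, 10 passed, 6 upward and 4 downward. Cholesterol synthesis genes tested lower, with 8 of 21 called lower, 18 lower adjusted over the list alone and a median log2 fold change of -0.2 (adjusted p = 7.24e-12, and adjusted p = 0.19 with an estimated correlation). Hmgcs1, of the mevalonate pathway, fell by 0.321 ± 0.0581. Mitosis genes tested higher, with 9 of 18 called, 16 adjusted over the list alone and a median of 0.31 (adjusted p = 7.24e-12, and adjusted p = 0.21 with an estimated correlation). Top2a rose by 0.41 ± 0.0764 and Kif20a by 0.42 ± 0.0833. DNA replication genes had 4 of 17 called higher, among them Mcm3 (0.36 ± 0.0783) and Pcna (0.23 ± 0.0632), 10 adjusted over the list alone and a median of 0.21 (adjusted p = 2.83e-06, and adjusted p = 0.35 with an estimated correlation). Immediate early and MAPK feedback genes tested higher, with 3 of 25 called, 11 higher and 1 lower adjusted over the list alone and Fos at 0.66 ± 0.106 (adjusted p = 6.98e-05, and adjusted p = 0.21 with an estimated correlation). Epidermal growth factor ligands and wound repair genes had 4 of 18 higher and 1 lower, 7 and 1 adjusted over the list alone, with the cytokine Lif at 0.49 ± 0.0764 and the ligand Areg at 0.46 ± 0.0983 (adjusted p = 6.46e-05, and adjusted p = 0.21 with an estimated correlation).

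The remaining lists past the threshold in PTSO against control held fewer called genes. Aryl hydrocarbon receptor targets tested higher, with 2 of 6 called, Cyp1b1 (0.54 ± 0.065) and Tiparp (0.77 ± 0.146), and 3 adjusted over the list alone (adjusted p = 0.000863, and adjusted p = 0.21 with an estimated correlation). The ATF4 integrated stress response list tested upward with 3 of 20 higher and 2 lower, 4 and 2 adjusted over the list alone (adjusted p = 0.00699, and adjusted p = 0.39 with an estimated correlation). Its members moved apart: Ppp1r15a, a phosphatase subunit that restores translation, rose by 0.5 ± 0.0697 and Atf3 by 0.59 ± 0.0964, while Asns, asparagine synthetase, fell by 0.384 ± 0.0711. Antigen presentation genes tested lower, with 3 of 12 called and 5 adjusted over the list alone, among them the peptide-loading genes Tapbp (-0.25 ± 0.0567) and Tap2 (-0.58 ± 0.159), at adjusted p = 0.000414, and adjusted p = 0.21 with an estimated correlation. Interferon-stimulated genes had 1 of 23 called lower, and 1 adjusted over the list alone, the RNA sensor Ddx58 (-0.45 ± 0.101), with a median of -0.25 (adjusted p = 0.00699, and adjusted p = 0.21 with an estimated correlation). Wnt targets and intestinal stem cell genes had 1 of 11 lower, Notum (-1.15 ± 0.275), and 2 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.45 with an estimated correlation).

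Lists that did not pass in PTSO against control also held called genes. Within the 29 NRF2 targets, Txnrd1, thioredoxin reductase (0.38 ± 0.0668), and Hmox1, heme oxygenase (0.36 ± 0.0882), were higher. The adjusted p of that list was 0.513, with 3 higher and 2 lower adjusted over the list alone. The unfolded protein response had 2 of 16 called lower, p53 targets 2 of 17 lower, and NF-kB targets 1 of 25 higher and 2 lower. The chaperone Hspa8 fell by 0.198 ± 0.0386, and the alarmin cytokine Il33 by 0.29 ± 0.0489. Of 14 tight junction and adhesion genes, 2 were called higher, Epcam (0.29 ± 0.0429) and Cldn4 (0.22 ± 0.0439). A further 3 were called lower, among them Tjp3 (-0.6 ± 0.107). Adjusted over the list alone, 3 were higher and 6 lower, and the median of the list was -0.14. The mitochondrial 16S ribosomal RNA gene mt-Rnr2 rose by 0.52 ± 0.0861.

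The number of genes called in PTSO against control rested on single libraries. It was 3637 without control library 1, 165 without control library 2, 222 without control library 3, 177 without PTSO library 2, 223 without PTSO library 3 and 77 without control libraries 2 and 3, and 46 with only the 6 libraries compared in the fit. Of the 802 genes, 119 kept the call whichever library was left out, 53 higher and 66 lower. Of the 41 called genes named here, 18 did so: Hspa1a, P2rx7, Selenoh, Selenow, Gpx1, Depp1, Ccdc33, Hmgcs1, Cyp1b1, Fos, Ppp1r15a, Atf3, Asns, Lif, Txnrd1, Il33, Epcam and Tjp3. Of the others, 19 lost it without control library 2 (adjusted p up to 0.189), 16 without control library 3 (up to 0.201), 21 without PTSO library 2 (up to 0.194), 19 without PTSO library 3 (up to 0.136), 5 without PTSO library 1 (up to 0.11) and 1 to 3 without a library of the groups that received antigens (up to 0.0728). Of the 41, 9 stayed called without control libraries 2 and 3 together: P2rx7, Selenoh, Selenow, Gpx1, Cyp1b1, Fos, Ppp1r15a, Hspa8 and Epcam. Adjusted p was then 0.228 for Hspa1a, 0.351 for Depp1, 0.426 for Ccdc33 and 0.214 for Hmgcs1, and the value of Kcnj2 was -0.67 and that of Prss35 -0.43.

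Without control libraries 2 and 3, the cholesterol synthesis, mitosis, immediate early, antigen presentation and aryl hydrocarbon receptor lists passed in the same direction (adjusted p from 8.3e-12 to 0.042). ATF4, interferon, wound repair, DNA replication and Wnt lists did not (0.22 to 0.53), and the ATF4 and Wnt lists then had the opposite direction. In PTSO against control 6 further lists passed in that fit: ribosomal proteins (2.4e-09), NRF2 targets (0.0094), NF-kB targets (0.026), proteasome subunits (0.029) and the unfolded protein response (0.044) downward, and glycolysis and hypoxia (1.6e-08) upward. In that fit with an estimated correlation 0 lists passed in PTSO against control, at adjusted p-values from 0.1 to 0.78. The ATF4 list held its call without 10 of the 12 libraries and the Wnt list without 11, with the highest adjusted p (0.12 and 0.13) without control library 3.

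PTSO + T. muris against T. muris asks what the compound changed in cells that also received the antigens, and it uses no control library in the contrast. The rises with the smallest adjusted p were again Selenow, from 35 ± 3.46 to 96.3 ± 3.5 CPM (log2 fold change 1.46 ± 0.0837, adjusted p = 4.29e-09), Selenoh, from 29.6 ± 2.38 to 70.8 ± 4.37 CPM (1.25 ± 0.085), and Gpx1, from 197 ± 4.97 to 346 ± 6.53 CPM (0.81 ± 0.0476, adjusted p = 3.68e-09). P2rx7 rose 10.2-fold, from 0.653 ± 0.384 to 6.26 ± 0.505 CPM. Hspa1a had 8 counts in the T. muris libraries together, 6 of them in T. muris library 1. This is 0.104 CPM with an interval of 0.045 to 0.205. With both treatments Hspa1a had 431 counts, 6.03 CPM with an interval of 5.47 to 6.62. Its paralog Hspa1b rose by 1.4 ± 0.234 (adjusted p = 0.0466), and the sum of the paralogs was 27.3 ± 2.26 and 77.2 ± 8.59 CPM. The mitochondrial ribosomal RNA genes mt-Rnr2 (0.86 ± 0.0867) and mt-Rnr1 (0.45 ± 0.0601) rose, as did Igsf11 (0.46 ± 0.0979). Reads of mt-Rnr1 and mt-Rnr2 can also come from nuclear copies.

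The largest falls in this comparison were Chodl (-1.03 ± 0.166), the vitamin D receptor gene Vdr (ENSMUSG00000022479), from 21.6 ± 2.43 to 10.6 ± 2.06 CPM (-1.02 ± 0.125), the adenylate kinase gene Ak5 (-0.96 ± 0.143), Cdh3, which encodes P-cadherin (-0.79 ± 0.109), Clca3b (ENSMUSG00000037033), from 58.7 ± 1.73 to 34.6 ± 0.818 CPM (-0.76 ± 0.0625), Glipr2 (-0.74 ± 0.147), the sodium pump subunit gene Atp1b1 (-0.66 ± 0.11) and the ceruloplasmin gene Cp (-0.61 ± 0.106). In all, 94 genes were called, 35 higher and 59 lower, and 10 changed by at least 1 on the log2 scale. Called list members were the chaperones Hspa8 (-0.19 ± 0.0386) and Hspb1 (0.23 ± 0.0484), the stress genes Ppp1r15a (0.37 ± 0.0698), Ddit4 (0.3 ± 0.0579) and Nupr1 (-0.31 ± 0.0612), Il33 (-0.29 ± 0.0489), the immediate early genes Junb (0.25 ± 0.053) and Ier2 (0.28 ± 0.0629), the junction genes Epcam (0.22 ± 0.0429) and Cldn4 (0.23 ± 0.044), Cyp1b1 (0.39 ± 0.0649) and the glutathione transferase Gsta4 (-0.57 ± 0.13).

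In PTSO + T. muris against T. muris, 6 lists passed. Cholesterol synthesis genes tested lower, with 0 of 21 called, 5 lower adjusted over the list alone and a median of -0.1 (adjusted p = 2.27e-07, and adjusted p = 0.3 with an estimated correlation). Sqle was at -0.22 ± 0.0581 (adjusted p = 0.104). All 18 mitosis genes had values above 0 and none was called, also adjusted over the list alone, with a median of 0.16 (adjusted p = 1.15e-07, and adjusted p = 0.37 with an estimated correlation). Ccnb1 was at 0.17 ± 0.0611 and Bub1 at 0.21 ± 0.0803. Glycolysis and hypoxia genes tested higher, with 0 of 21 called, 2 higher adjusted over the list alone and a median of 0.12 (adjusted p = 3.35e-06, and adjusted p = 0.37 with an estimated correlation); Hk2 was at 0.2 ± 0.054 and Adm at 0.64 ± 0.161. The endoplasmic reticulum unfolded protein response list tested lower, with 0 of 16 called, 0 adjusted over the list alone, a median of -0.09 and Calr at -0.14 ± 0.0422 (adjusted p = 0.000124, and adjusted p = 0.067 with an estimated correlation). NRF2 targets tested lower, with 1 of 29 called lower, 2 higher and 3 lower adjusted over the list alone and a median of -0.09 (adjusted p = 0.0158, and adjusted p = 0.37 with an estimated correlation). Txnrd1 had a value of 0.24 ± 0.0667 and was not called. Immediate early genes tested higher, with 2 of 25 called and 5 adjusted over the list alone (adjusted p = 0.00117, and adjusted p = 0.32 with an estimated correlation).

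The shared spread in the fit includes the control libraries, and the count of 94 genes rose to 371 without control library 1, 162 without control library 3, 425 without control libraries 2 and 3 and 479 with only the 6 libraries compared. The count fell to 70 without control library 2, and to 63, 64 and 65 without PTSO library 1, 2 or 3. It was 27, 32 and 25 without T. muris library 1, 2 or 3. Without library 1, 2 or 3 of PTSO + T. muris it was 30, 23 and 40. The list count was 10 without T. muris library 1. The calls of 20 genes held whichever library was left out, 8 higher and 12 lower. Of the 29 called genes named for PTSO + T. muris against T. muris, P2rx7, Selenow, Selenoh, Gpx1, mt-Rnr1, mt-Rnr2, Vdr, Ak5, Cdh3 and Clca3b were among them. Hspa1a lost its call without each of the T. muris libraries in turn. Calls among the named genes ended in 16, 15 and 16 cases without T. muris library 1, 2 or 3 (adjusted p up to 0.274), in 16, 17 and 10 cases without library 1, 2 or 3 of PTSO + T. muris (up to 0.282) and in 1 to 5 cases without a PTSO library or control library 2 or 3 (up to 0.0807).

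**Figure D2:**
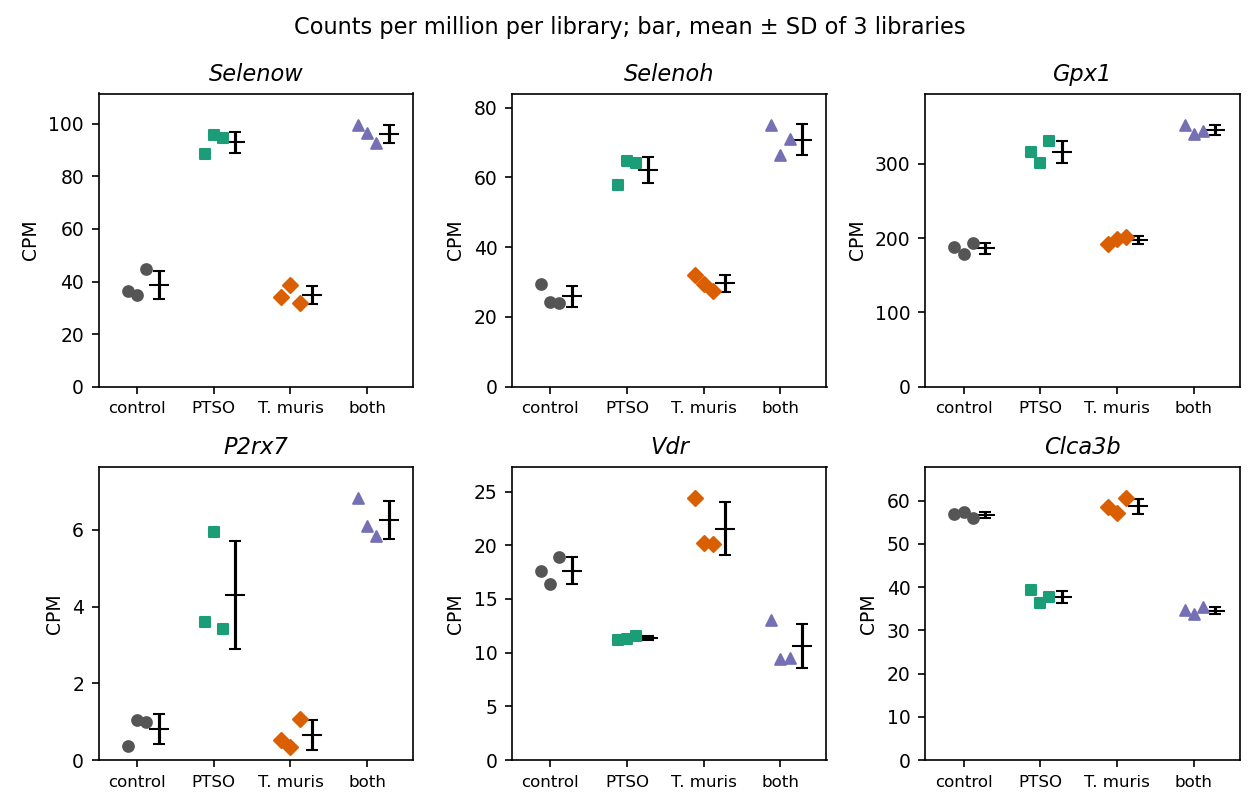
Counts per M of 6 genes in each library, by group, with mean ± SD of 3 libraries beside the points; the vertical axes start at 0. Selenow, Selenoh, Gpx1 and P2rx7 are higher, and Vdr and Clca3b lower, in all 6 PTSO-treated libraries than in all 6 others; Selenow averages 92.9 and 96.3 CPM with PTSO against 38.8 and 35 CPM without it.

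The PTSO effect was compared between cells without and with antigens. Of the 94 genes called with antigens, 92 had the same sign without them, and 61 were called in both backgrounds. Of these, 25 were higher in both, where independence would give 0.825, and 36 were lower in both, where it would give 1.71. Both comparisons take a gene's spread from the same fit. Genes with a small spread are thus called more readily in both, and independence sets too low a bar. The signs do not depend on this, and 0 genes were called in opposite directions. Over the 94 genes the log2 fold changes correlated at 0.633, and over all 15267 genes at r = 0.202, with a Spearman rho of 0.252. Among the 61 were Vdr (-0.63 without antigens and -1.02 with them), Clca3b (-0.59 and -0.76), Cp (-0.65 and -0.61), Atp1b1 (-0.6 and -0.66), Cyp1b1 (0.54 and 0.39), Ppp1r15a (0.5 and 0.37) and Il33 (-0.29 and -0.29); their values without antigens were looked up after the overlap was seen for Vdr, Clca3b, Cp and Atp1b1. In 44 of the 61, 19 higher and 25 lower, the call against control held whichever control library was left out. Without control libraries 2 and 3 the correlation over the genes then tested was 0.0965, and with any single library left out it was 0.138 to 0.19. The low-count filter was run again in these fits. Their genes differ, so the drop cannot be laid to the libraries alone.

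**Figure D3:**
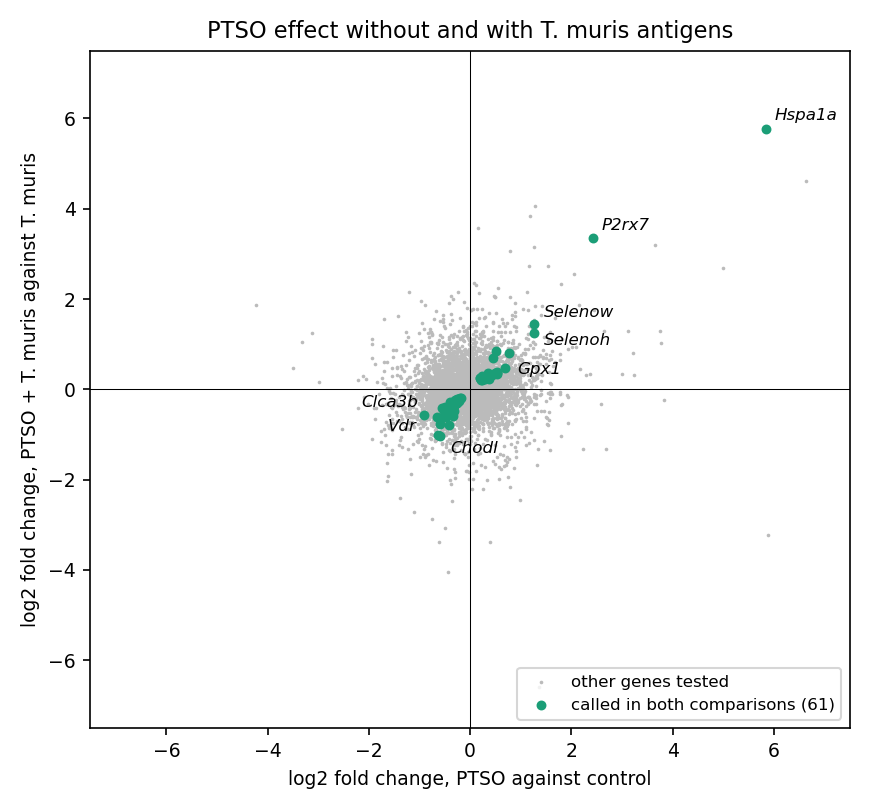
Log2 fold change of PTSO against control (horizontal axis) and of PTSO + T. muris against T. muris (vertical axis) for 15267 genes, with the 61 genes called in both comparisons in green. The 61 green points lie in the quadrants where both changes have the same sign, 25 up and 36 down.

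T. muris against control asks what the antigens alone changed. Genes of glycolysis and hypoxia tested lower: 14 of 21 were called lower, 17 adjusted over the list alone, with a median log2 fold change of -0.25 (adjusted p = 3.23e-12, and adjusted p = 0.23 with an estimated correlation). The glucose transporter gene Slc2a1 fell by 0.314 ± 0.0553, Pfkp, a phosphofructokinase, by 0.505 ± 0.0834, and Adm, adrenomedullin, by 0.84 ± 0.16. DNA replication genes tested higher, with 10 of 17 called and 15 adjusted over the list alone, among them Mcm7 (0.25 ± 0.0615) and the histone mRNA binding gene Slbp (0.27 ± 0.0662), at adjusted p = 1.31e-10, and adjusted p = 0.23 with an estimated correlation. Mitosis genes tested higher, with 7 of 18 called and 13 adjusted over the list alone, such as Ccna2 (0.32 ± 0.0768) and Plk1 (0.27 ± 0.0695), at adjusted p = 1.32e-08, and adjusted p = 0.27 with an estimated correlation. NRF2 targets tested higher, with 7 of 29 called, 12 higher and 1 lower adjusted over the list alone (adjusted p = 1.03e-05, and adjusted p = 0.23 with an estimated correlation). The cystine transporter gene Slc7a11 went from 88 ± 18.3 to 139 ± 2.67 CPM, and Pgd, of the pentose phosphate pathway, rose by 0.31 ± 0.0657.

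Further lists passed in T. muris against control. Proteasome subunits tested higher, with 2 of 27 called, Psmc2 (0.22 ± 0.0567) and Psma3 (0.19 ± 0.0552), 13 adjusted over the list alone and 26 above 0 (adjusted p = 1.21e-07, and adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis genes tested lower, with 5 of 21 lower, 1 higher and 12 lower adjusted over the list alone and Hmgcs1 at -0.28 ± 0.0582 (adjusted p = 6.09e-05, and adjusted p = 0.23 with an estimated correlation). Aryl hydrocarbon receptor targets tested higher, with 2 of 6 called, 4 adjusted over the list alone and Aldh3a1 at 0.74 ± 0.154 (adjusted p = 0.000339, and adjusted p = 0.23 with an estimated correlation). The ATF4 list tested higher, with 4 of 20 higher and 2 lower, 12 and 2 adjusted over the list alone, including Sesn2 (0.51 ± 0.119) upward and Ddit4 (-0.31 ± 0.0578), an inhibitor of mTOR signalling, downward (adjusted p = 0.000412, and adjusted p = 0.27 with an estimated correlation). Wnt targets tested lower, with 3 of 11 called, 1 higher and 7 lower adjusted over the list alone and the stem cell marker Lgr5 at -0.58 ± 0.147 (adjusted p = 0.00164, and adjusted p = 0.28 with an estimated correlation). Ribosomal proteins tested higher with 0 of 31 called, 0 adjusted over the list alone and Rplp0 at 0.16 ± 0.051 (adjusted p = 0.00617, and adjusted p = 0.55 with an estimated correlation). Enterocyte genes tested lower with 1 of 5 called, the sodium-proton exchanger gene Slc9a3 (-1.06 ± 0.309), and 2 adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.23 with an estimated correlation). Wound repair genes had 1 of 18 called higher, 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.0211, and adjusted p = 0.29 with an estimated correlation). The unfolded protein response list had 2 of 16 higher, Hyou1 (0.19 ± 0.0508) and Manf (0.2 ± 0.0598), and 6 adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.23 with an estimated correlation).

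The largest rises in T. muris against control were Cd53 (1.2 ± 0.24), Anks1b (1.02 ± 0.253), Vgf (0.96 ± 0.235), the cytokine gene Il24 (0.91 ± 0.178), Etv5, a transcription factor downstream of MAPK signalling (0.88 ± 0.148), Cenpp (0.77 ± 0.199), the MAPK phosphatase gene Dusp6 (0.75 ± 0.177) and Aldh3a1. The largest falls were Tmem150a (-2.49 ± 0.612, and -4 without T. muris library 1, which held 71 of its counts against 8 and 7 in the others of that group), Ccdc33 (-1.57 ± 0.282), Ascl4 (-1.4 ± 0.389), Car11 (-1.18 ± 0.253), C1rl (-1.18 ± 0.281), Serpinb10 (-1.15 ± 0.227), Cib3 (-1.1 ± 0.248) and Wnk2 (-0.99 ± 0.225). Ascl4 had 60, 79 and 167 counts in control libraries 1, 2 and 3. NF-kB targets and inflammatory cytokines did not pass as a list (adjusted p = 0.955), with 2 of 25 called higher and 2 lower, the same numbers adjusted over the list alone; the chemokine gene Cxcl5 rose by 0.44 ± 0.114 and Csf1 fell by 0.454 ± 0.0812. In all, 969 genes were called, 445 higher and 524 lower, 20 of them by at least 1 on the log2 scale.

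These calls depended on the control libraries. The count in T. muris against control was 4044 without control library 1, 5 without control library 2, 66 without control library 3, and 8 without control libraries 2 and 3. It was 2, 24 and 58 without T. muris library 1, 2 or 3, 568 without library 2 of PTSO + T. muris, and 1 with only the 6 libraries compared. The call of 1 gene held whichever library was left out, that of Lamb2, a laminin subunit gene, which fell by 0.351 ± 0.0501 and was chosen after its values were seen. Of the 37 called genes named, 36 lost the call without control library 2 (adjusted p up to 0.25), 30 without control library 3 (up to 0.236), 35, 35 and 32 without T. muris library 1, 2 or 3 (up to 0.219), and 3 to 7 without a library of a PTSO-treated group (up to 0.0681). Of the 37, 1 stayed called without control libraries 2 and 3 together, Slc7a11, at 0.38 (adjusted p = 0.00598). Without control libraries 2 and 3, the glycolysis, NRF2, unfolded protein response, DNA replication, cholesterol, aryl hydrocarbon receptor, proteasome and mitosis lists passed in the same direction (adjusted p from 5.3e-10 to 0.021). The ATF4, wound repair, Wnt and enterocyte lists did not (0.13 to 0.95), wound repair then having the opposite direction, and ribosomal proteins passed in the opposite direction (0.0029). With an estimated correlation 0 lists passed in that fit, at 0.061 to 0.96. Single libraries ended the unfolded protein response call (adjusted p = 0.14 without control library 1), the wound repair call (0.074 without control library 3) and the ribosomal protein call (0.15 without control library 2).

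PTSO + T. muris against PTSO asks what the antigens changed in cells that had received the compound. By edgeR 0 genes were called, with 932 at an unadjusted p under 0.05, while voom called 0 and DESeq2 15. The smallest p-values were those of Txnip, a thioredoxin-binding protein gene (0.4 ± 0.0823), the bicarbonate transporter gene Slc4a4 (-0.37 ± 0.0755), Nudt8 (-4.17 ± 0.895, below 1 CPM in every group mean) and Hk2 (-0.24 ± 0.0535), each with adjusted p = 0.375, not past the threshold. The count was 36 without control library 1, 1 without PTSO library 3, 1 without T. muris library 1, 80 without control libraries 2 and 3, and 34 with only the 6 libraries compared. Over all genes the T. muris effect without and with PTSO correlated at r = 0.116, with a Spearman rho of 0.263. Without control libraries 2 and 3 it was 0.0294, over a different set of genes, since the low-count filter was run again.

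In PTSO + T. muris against PTSO, 7 lists passed, each in the direction it had in T. muris against control. Glycolysis and hypoxia genes tested lower, with 19 of 21 at or below 0, 4 lower adjusted over the list alone and a median of -0.12 (adjusted p = 1.43e-08, and adjusted p = 0.51 with an estimated correlation). DNA replication genes tested higher, with all 17 above 0, 0 called adjusted over the list alone and a median of 0.13 (adjusted p = 8.06e-07, and adjusted p = 0.51 with an estimated correlation). The others upward, each with 0 called adjusted over the list alone, were proteasome subunits (25 of 27 above 0, adjusted p = 2.75e-06), mitosis (16 of 18, adjusted p = 5.03e-05), NRF2 targets (23 of 29, adjusted p = 0.00133), ribosomal proteins (24 of 31, adjusted p = 0.0194) and the unfolded protein response (13 of 16, adjusted p = 0.0288). With an estimated correlation their adjusted p-values were 0.51 to 0.75. The unfolded protein response call held without 8 of the 12 libraries, with the highest adjusted p (0.085) without library 1 of PTSO + T. muris, and the ribosomal protein call without 9, with the highest (0.47) without PTSO library 2.

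**Figure D4:**
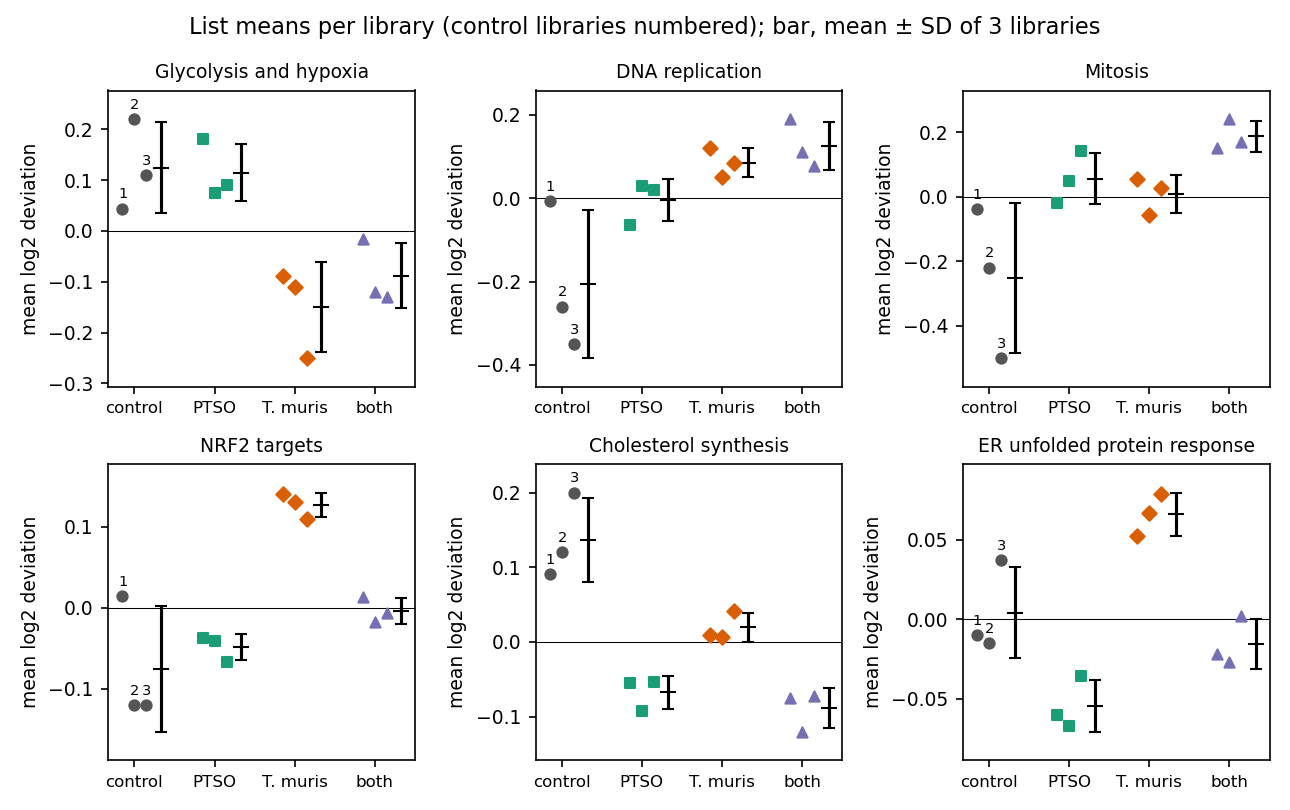
Mean log2 deviation of the tested genes of 6 lists from their average over the 12 libraries, per library and group, with mean ± SD of 3 libraries and the control libraries numbered; vertical scales differ between panels. Glycolysis and hypoxia lies at -0.25 to -0.015 in the 6 libraries with antigens and at 0.044 to 0.22 in the 6 without, and cholesterol synthesis at -0.12 to -0.054 in the 6 with PTSO and at 0.007 to 0.2 in the 6 without.

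PTSO + T. muris against control combines both treatments. The largest rises were Hspa1a (5.92 ± 0.79), Atp6v1c1, a proton pump subunit gene (3.24 ± 0.816, from 5.6 ± 1.99 to 52.8 ± 26.4 CPM), P2rx7 (2.96 ± 0.356) and Prl2c3 (1.6 ± 0.407), which belongs to a cluster of similar genes that can share reads. The largest falls were Serpinb10 (-1.63 ± 0.234), Ccdc33 (-1.61 ± 0.285), Atoh8 (-1.54 ± 0.378) and Cib3 (-1.54 ± 0.255). Of the genes tested, 2554 were called, 1203 higher and 1351 lower, and 147 changed by at least 1 on the log2 scale. Mitosis tested higher with 15 of 18 called and 17 adjusted over the list alone (median 0.4, adjusted p = 8.16e-14), DNA replication with 13 of 17 and 14 adjusted over the list alone (adjusted p = 2.63e-10), and cholesterol synthesis lower with 12 of 21 and 17 adjusted over the list alone (adjusted p = 5.17e-10). Each of these had an adjusted p = 0.3 with an estimated correlation.

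In all, 15 lists passed in PTSO + T. muris against control, 9 upward and 6 downward. Besides those above, the upward ones were proteasome subunits (adjusted p = 2.99e-05), aryl hydrocarbon receptor targets (0.000237), wound repair (0.00656), immediate early genes (0.00794), the ATF4 list (0.00909), NRF2 targets (0.0286) and ribosomal proteins (0.0399). The downward ones were glycolysis and hypoxia (0.00021), Wnt targets (0.00633), interferon-stimulated genes (0.00642), antigen presentation (0.00642), and mucus and goblet cell genes (0.0399), with 2 of 4 called and 3 adjusted over the list alone. With an estimated correlation no list passed, at adjusted p-values from 0.3 to 0.69.

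The count in PTSO + T. muris against control was 4799 without control library 1, 990 without control library 2, 1089 without control library 3, 1048 and 1300 without library 1 or 2 of PTSO + T. muris, 204 without control libraries 2 and 3, and 864 with only the 6 libraries compared. Hspa1a, P2rx7, Serpinb10, Ccdc33 and Cib3 kept their calls whichever library was left out. Without control library 2, 3 of the 8 named genes lost the call (adjusted p up to 0.126), without control library 3 also 3 (up to 0.12), and without library 1, 2 or 3 of PTSO + T. muris 3, 3 and 1 (up to 0.106). P2rx7 and Serpinb10, 2 of the 8, stayed called without control libraries 2 and 3 together. Without control libraries 2 and 3, the cholesterol, mitosis, DNA replication, aryl hydrocarbon receptor and antigen presentation lists passed in the same direction (adjusted p from 1.8e-13 to 0.046), and ribosomal proteins in the opposite one (0.016). The other 9 lists did not pass: NRF2 targets (0.86), the ATF4 list (0.94, then downward), interferon-stimulated genes (0.15), immediate early genes (0.079), wound repair (0.6), mucus genes (0.47), glycolysis and hypoxia (0.94), Wnt targets (0.36) and proteasome subunits (0.17). NF-kB targets passed downward in that fit (0.011), and with an estimated correlation 0 lists passed in it, at 0.077 to 0.98. With single libraries left out, the highest adjusted p was 0.06 for NRF2 targets, 0.069 for mucus genes and 0.35 for ribosomal proteins, each without control library 2, and 0.051 for the ATF4 list without control library 3. These calls held without 11, 7, 8 and 11 of the 12 libraries.

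The interaction asks whether the PTSO effect differed between cells with and without antigens. By edgeR 0 genes were called, with 1181 at an unadjusted p under 0.05, while voom called 0 and DESeq2 4. The smallest p-values were those of Tmem150a (6.09 ± 0.95), the pseudogene Gpx4-ps2 (0.39 ± 0.0847), Cdkn2a, a cell cycle inhibitor gene (0.36 ± 0.0833), and Il24 (-1.02 ± 0.247), each with adjusted p = 0.609, not past the threshold. The count was 1279 without control library 1, 1 without PTSO library 3, 2 without T. muris library 1, 1 without T. muris library 2 and 1 without control libraries 2 and 3. Camera called 12 lists, 5 upward and 7 downward, and 6 without control library 3. With an estimated correlation 0 passed, at adjusted p-values from 0.44 to 0.92, and without control libraries 2 and 3 none of the 12 did.

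Several lists passed in none of the 6 tests. In PTSO against control, T. muris against control and PTSO + T. muris against T. muris, the adjusted p was 0.261, 0.267 and 0.959 for the heat shock response, 0.749, 0.477 and 0.658 for the metal response, 0.27, 0.988 and 0.255 for the type 2 epithelial response, 0.261, 0.164 and 0.908 for tight junction and adhesion, and 0.319, 0.204 and 0.908 for p53 targets. It was 0.532, 0.955 and 0.118 for NF-kB targets, which passed downward against control without control libraries 2 and 3 with PTSO (0.026, and 0.15 with an estimated correlation) and with both treatments (0.011, and 0.12), and 0.41, 0.315 and 0.959 for mitochondrially encoded transcripts. In the same order, the fibroblast and endothelial markers had 0.532, 0.988 and 0.0771, with 5 of 14 genes tested and a median of -0.61 for PTSO + T. muris against T. muris. Only 2 of 13 antimicrobial defence genes and 2 of 10 leukocyte markers had enough counts, so those lists were not tested; their medians in PTSO against control were 0.33 and -0.09. Median, mean and test differed in sign in PTSO against control for the metal response (median -0.02, mean 0.04, test upward) and NF-kB targets (-0.05, 0.05, downward). In T. muris against control they did so for the metal response (0.01, -0.11, downward) and the type 2 response (-0.04, 0.0033, upward), and in PTSO + T. muris against T. muris for heat shock (-0.04, 0.35, downward), ribosomal proteins (0.0084, -0.01, downward) and mitochondrial transcripts (-0.08, -0.04, upward). In PTSO + T. muris against PTSO they did so for heat shock, metal, antigen presentation, immediate early and mitochondrial lists, and in the interaction for mucus genes.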

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

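The fit without control libraries 2 and 3, the removal of GC and length trends, the test of sequencing depth and the count of splits by the place of control libraries 2 and 3 were chosen after the results were seen. For the other tests of explanations of the control libraries, what each should show was written down before its outcome. The test of the difference between the PTSO effects with and without antigens called 12 lists. The median difference, as log2 with antigens minus without, was -0.085 for NRF2 targets, -0.24 for the ATF4 list, 0.11 for antigen presentation, -0.17 for wound repair, 0.081 for cholesterol synthesis, 0.14 for glycolysis and hypoxia, -0.16 for mitosis, -0.18 for DNA replication, -0.29 for aryl hydrocarbon receptor targets, 0.24 for Wnt targets, -0.047 for proteasome subunits and 0.46 for enterocyte genes. Adjusted p-values were 0.000145 to 0.0352 with the preset correlation and 0.44 to 0.57 with an estimated one. Without control libraries 2 and 3 they were 0.18 to 0.87, and the ribosomal protein list (adjusted p = 4e-08) was the only one to pass. Without control library 3 alone, 6 lists passed.

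Control libraries 2 and 3 stood apart from the other 10 libraries. Sequencing depth as the cause is argued against, since the more distant of their totals, 24.6 M counts, lies inside the range of 16.7 to 34.5 M of the others. A trend with GC content or gene length is argued against: with both trends removed from each library, the gap between control libraries 2 and 3 and the other 10 on component 1 kept 0.991 of its size. A count of called genes, planned first for this, was put aside, since leaving out a control library moves it either way. An exchange of libraries with another group is argued against by the correlations, as no library of another group lay closer to control libraries 2 and 3 than to its own group (largest excess -0.0026). Whether control library 1 is a mislabelled T. muris library could not be told. Each such test sets 1 library against a group and takes its spread from the other groups in the fit. In Selenow, control library 1 had 36.3 CPM, and the PTSO-treated libraries had 88.45 CPM or more. The prediction written beforehand for a mislabelled T. muris library covered genes, not lists, and was met. Control library 1 differed from the 3 T. muris libraries in 1 gene, where a T. muris library differed from the others of its group in 0 to 2. It differed from them in 9 lists, where those differed in 0 or 1. From the PTSO libraries it differed in 55 genes and 9 lists, and from those with both treatments in 168 genes and 6 lists. By lists, control library 1 was thus no nearer to the T. muris libraries than to the other treated groups. Separate culture or handling of the control libraries stays open, as the labels do not record it.

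Every split of the 6 libraries in a comparison into 3 against 3 was tested. The 10 splits are too few for a share under 0.05. In PTSO against control the real split called 802 genes and the highest other 428; 1 of the 10 splits reached the real count. The highest other put control libraries 2 and 3 with PTSO library 1. In T. muris against control the values were 969 and 1, with 1 of 10 splits reaching the real count, in PTSO + T. muris against T. muris 94 and 1, with 1 of 10, and in PTSO + T. muris against control 2554 and 9, with 1 of 10. The highest other also kept control libraries 2 and 3 together in T. muris against control (1 gene) and in PTSO + T. muris against control (9 genes). Keeping them together therefore did not by itself bring a high count. Where the real count was 0 the splits decide nothing, since each reaches it: 10 of 10 in PTSO + T. muris against PTSO, with 1 as the highest other, and 100 of 100 splits drawn for the interaction. The highest of the latter called 792 genes. It kept the 3 control libraries in 1 group and the 3 T. muris libraries in another. Its contrast thus set the 6 libraries without PTSO against the 6 with PTSO. Of the splits other than the real one, 4 of 15 with control libraries 2 and 3 in the same group called at least 10 genes and 0 of 84 with them in different groups did. The split with 792 genes is among the 4, and the PTSO effect can account for it. What the rest of the 4 set against each other was not examined. Any gene was called in 8 of the 15 (median 1) and in 4 of the 84 (median 0). Calls thus came more often with control libraries 2 and 3 together. How much of this is the PTSO effect was not tested.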

How the results depend on the processing

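The fit without control libraries 2 and 3 and the GC and length offsets were chosen after seeing the data; the cause of the changes below was not tested unless fewer genes or samples make it. Counts are in the order PTSO against control, T. muris against control, PTSO + T. muris against T. muris, PTSO + T. muris against PTSO, PTSO + T. muris against control, and interaction. DESeq2 called 1544, 1960, 195, 15, 3051 and 4 genes, voom 834, 1045, 90, 0, 2507 and 0, and edgeR without a filter 1728, 2063, 249, 42, 2963 and 45. DESeq2 size factors, the stricter filter and the offsets kept each count within 1.5 times. With only the groups compared the counts were 46, 1, 479, 34 and 864, and without control libraries 2 and 3 they were 77, 8, 425, 80, 204 and 1. A minimum absolute log2 fold change of 1 left 37, 20, 10, 0, 147 and 0. With the replicate number as a block they were 904, 1246, 87, 0, 2674 and 1. The residual correlation between libraries of the same number had a median of 0.0015, from -0.092 to 0.15 over 18 pairs. This shows no pairing by number but cannot exclude it. Leaving out each library in turn gave 165 to 3637, 2 to 4044, 23 to 371, 0 to 36, 990 to 4799 and 0 to 1279 genes.

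Lists past the threshold were 10, 13, 6, 7, 15 and 12 as reported, and 0 in each comparison with an estimated correlation. Fry called 8, 12, 3, 0, 13 and 0, and the fits without control libraries 2 and 3 gave 11, 9, 9, 9, 7 and 1. Those fits with an estimated correlation, also chosen after seeing the data, gave 0, 0, 0, 1, 0 and 0. With the block they were 10, 14, 6, 8, 15 and 12, and with DESeq2 size factors 10, 13, 6, 7, 15 and 12. Leaving out each library gave 8 to 15, 12 to 15, 6 to 10, 5 to 9, 12 to 16 and 6 to 14. The correlation of the PTSO effect was 0.28 with the stricter filter, 0.252 as Spearman's rho, 0.205 with the block, 0.0965 without control libraries 2 and 3, and 0.138 to 0.19 with each library left out. That of the T. muris effect was 0.201, 0.263, 0.116 with the block, 0.0294, and 0.0739 to 0.153. With libraries left out, the low-count filter was run again, so those correlations are over other genes. No called gene that is named reversed its direction in these settings. Of the called genes named in PTSO against control, T. muris against control and PTSO + T. muris against T. muris, 41 of 41, 36 of 37 and 29 of 29 were also called by DESeq2. With only the groups compared 12 of 41, 0 of 37 and 29 of 29 stayed called, and without control libraries 2 and 3 these were 9, 1 and 29. Depth limits genes such as Hspa1a and P2rx7, which had 7 and 61 counts over the control libraries.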

Other observations

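The tests of list means, of the selenoprotein family and of the ribosomal RNA features were chosen after the results were seen; the prediction for GC content and length was written before its result. Each list was also summarised by its mean log2 deviation per library, and the 6 libraries with a treatment were compared with the 6 without it by a two-sided exact permutation test within the levels of the other treatment. There were 400 permutations, so 0.005 is the smallest p they can give, and p-values were adjusted over 50 tests. Values after "then" are differences without control libraries 2 and 3. With PTSO, the means of 5 lists separated the 6 treated libraries from the 6 others: cholesterol synthesis (difference -0.16, then -0.13), interferon-stimulated genes (-0.16, then -0.095), heat shock (0.23, then 0.22), immediate early genes (0.18, then 0.11) and wound repair (0.11, then 0.051), each with permutation p = 0.005 and adjusted p = 0.019. The margin was narrow for interferon-stimulated genes (at most -0.024 with PTSO and at least -0.019 without) and immediate early genes (at least 0.016 and at most 0.0061). The paralogs Hspa1a and Hspa1b, which share reads, make the heat shock difference: without them it was -0.017 over 16 genes (permutation p = 0.48), with no separation. Camera did not call that list. Mitosis (0.24, then 0.14) and the unfolded protein response (-0.07, then -0.063) had the same p without full separation. Aryl hydrocarbon receptor targets (0.25, then 0.075, adjusted permutation p = 0.033), antigen presentation (-0.15, then -0.11) and the 5 fibroblast and endothelial markers (-0.21, then -0.13, both with adjusted permutation p = 0.042) also passed.

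With T. muris antigens, the means of 2 lists separated the 6 treated from the 6 other libraries: glycolysis and hypoxia (-0.24, then -0.2) and DNA replication (0.21, then 0.11), each with permutation p = 0.005 and adjusted p = 0.019. At the same p and without full separation, NRF2 targets (0.12, then 0.079), proteasome subunits (0.09, then 0.049) and the unfolded protein response (0.05, then 0.057) were higher, and the 3 metal response genes lower (-0.097, then -0.086). Aryl hydrocarbon receptor targets (0.29, then 0.11, adjusted permutation p = 0.033) and mitosis (0.2, then 0.09, adjusted permutation p = 0.042) also passed.

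Selenow, Selenoh and Gpx1 rose with PTSO in both backgrounds. A trend with GC content or length is argued against, because with offsets for both the 3 genes kept at least 0.982 of their log2 fold change in PTSO + T. muris against T. muris. A rise of all selenoprotein transcripts is argued against too: the median of the 18 others tested was -0.0053 with antigens, with quartiles of -0.17 and 0.076, and 0 were called higher and 1, Sephs2 (-0.57), lower. Without antigens the median was 0.028, with quartiles of -0.099 and 0.13; Txnrd1 (0.38) and Selenof (0.18) were called higher and Gpx3 (-0.83) lower. Reads shared with pseudogenes were not tested. An effect of PTSO on transcripts of these 3 genes may remain as a hypothesis.

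The mitochondrial ribosomal RNA genes rose with PTSO, mt-Rnr2 to 255 to 350 CPM in the 6 treated libraries against 167 to 212 in the others, and mt-Rnr1 to 303 to 380 against 248 to 289. A rise of all mitochondrially encoded transcripts is argued against, as the median of the 13 mitochondrial mRNAs was -0.12 in PTSO + T. muris against T. muris, where mt-Rnr1 was at 0.45. Carry-over of RNA without poly(A) tails in library preparation is a candidate explanation only if poly(A) selection was used, which was not checked here. Rn7sk, an abundant RNA without such a tail, was at 22 CPM or more in the 6 libraries with PTSO and at 21.8 CPM or less in the 6 without. The margin is small, and an effect of PTSO on these RNAs stays open.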
